A study of Caenorhabditis elegans with 6 samples.

How the data were processed

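Small RNAs of 18 to 28 nt from Caenorhabditis elegans adults were sequenced in 6 libraries, 1 for each of 6 genotypes, so no genotype had a replicate. Per the labels' protocols, the animals were grown on OP50 bacteria at 20 °C and collected 69 h after release from L1 arrest, and the RNA was treated with tobacco acid pyrophosphatase, which lets 5′-triphosphate siRNAs be ligated and cloned. Each deposited file lists read sequences with the whole-number count of reads of each, as the authors made it, with no normalization. Per the submitters' processing notes Bowtie was used; its version, the mapping settings and any filter on the reads are not given in the sources used here. Every sequence was 18 to 28 nt long, and 0.19% to 0.25% of the reads of a library held an undetermined base. Totals ran from 12762593 to 19233922 reads per library, so a count of 0 allowed a level of up to 0.156 to 0.235 RPM (3 counts of the total, in reads per 1000000 reads of the library). Intervals are 95% limits, exact Clopper-Pearson for shares, exact Poisson for rates and exact conditional binomial for ratios. They cover counting error only, with no spread between libraries. Reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for that error.

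Groups, tests, gene lists, the rule for named items and the main alternatives were fixed before the data were examined. They asked for siRNA counts per gene. No genome sequence was used here, so the fallback fixed for that case was followed: single sequences with at least 100 reads over the 6 libraries, starting with G and 22 nt long (22G) or 26 nt long (26G), were tested in place of genes. None of these sequences was given a gene name or a position, and the lists of Argonaute targets and of tissue genes were not analysed here. The levels of eri-6, eri-7 and arl-8 themselves, and siRNAs of lin-14, rol-6, col-10, lim-6 and sur-5, were not analysed here either. Library size was the total of all reads wherever reads matching the genome had been planned.

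The eri-6 comparison set 3 eri-6 mutant libraries (no transgene, sur-5::gfp, mgIs30) against 2 eri-6 wild-type libraries (sur-5::gfp, mgIs30). Libraries with different transgenes stood in for replicates, so a p-value measures the spread between these strains, with culture and library preparation included. The test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest), with TMM factors and filterByExpr at a minimum count of 10. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The test gives no standard error (SE). An approximate SE was taken as the absolute log2 change over the square root of the F statistic. For 26G sequences the library size was the total of reads, without TMM. DESeq2 1.42.0 and limma 3.58.1 (camera, with preset and estimated correlation) were also used. The arl-8 library was set against the same 2 wild-type libraries without a test: a 22G sequence counted as lower or higher when it differed at least 4-fold from both, in CPM over these sequences after TMM with 1 added, and its mean was at least 10 CPM. The same count was made for each control library. The 26G count in arl-8 used RPM with 0.2 added. Simulated lists for the overlap were a choice made after seeing the data. Named sequences were taken from the 10 with the largest fall or rise among the calls that went the same way in both within-transgene pairs; for miRNAs, the most abundant member of each fixed family was named. Other items named were chosen after their values were seen.

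Names came from sequences written from general knowledge and matched exactly on both strands. The coding sequence of GFP (717 nt, in the form used for worm expression) was fixed in advance. The bodies of lacZ (2750 nt searched) and bla (861 nt), the unc-54 3′ UTR (759 nt) and 3 GFP introns of 51 nt were added after the data had been seen, as were a panel of 70 miRNAs, counted by their first 20 nt, and the proteins below. Both ends of lacZ were left out because cloning vectors carry them. Sequences starting with G were also translated and matched, over at least 6 residues, to major sperm protein (MSP), histone H3, histone H4, actin and the Tc1 transposase. Each reversed protein served as background. 22G and 26G reads of these matches, and the shares of reads, were taken at 21 to 23 nt and 25 to 27 nt. Near-identical gene copies within a family cannot be told apart by such a match. As a further addition after seeing the data, sequences of 20 to 27 nt starting with G were joined into loci where they shared 18 nt on the same strand, and loci were tested like sequences.

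The tests were checked on simulated counts with known changes, drawn at a dispersion of 0.1 from the means and library sizes of the real data. The common dispersion fitted to the real 22G sequences was 0.197, so the shares below hold for less variable counts and may be too favourable. Among 15431 22G sequences, 50 were changed at each size: 96% of those with a log2 change of -4 were recovered, 60% of those at -2 and 6% of those at -1, and 1.7% of calls were false. Among 272 26G sequences, with 17 changed at each size, the recovered shares were 52.9% at -4, 70.6% at -2 and 29.4% at -1, with 9.3% of calls false. For the 70 miRNAs, all 5 changed by -4 and all 4 changed by -2 were recovered, and 1 of the 4 changed by -1. For 18599 22G loci with 50 changed at each size, the recovered shares were 100% at -4 and 64% at -2. For 3914 26G loci with 50 changed at each size they were 42% at -4 and 14% at -2. Alternatives covered DESeq2, other size factors and library sizes, filters on low counts, the transgene pairs as a block, the arl-8 library among the wild type, leaving out each library, other thresholds for arl-8, other length windows and the removal of first-base variants. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for the remaining steps.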

Results

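The series holds 6 small RNA libraries of adult worms, designed around small interfering RNAs (siRNAs) made against transgenes and siRNAs that depend on arl-8, a lysosomal small GTPase. Of these, 3 libraries came from eri-6 mutants; eri-6 encodes a helicase of the endogenous RNAi pathway. The labels of the eri-6; mgIs30 library conflict on its eri-6 allele, with mg379 in the title and mg369 in the strain field. An eri-6 strain without a transgene had been backcrossed 6 times and an arl-8 strain 4 times. Both transgenes, sur-5::gfp and mgIs30, were present in an eri-6 mutant and in an eri-6 wild-type strain. The mgIs30 array carries rol-6 and lin-14 sequences, a col-10::lacZ::lin-14 fusion and a lim-6::gfp::unc-54 fusion. The libraries held 12762593 reads (eri-6; mgIs30), 18858436 (eri-6; sur-5::gfp), 17629985 (sur-5::gfp), 19233922 (eri-6), 15063846 (arl-8) and 17673651 (mgIs30). Levels are given in RPM, reads per 1000000 reads of the library.

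The 3 eri-6 mutant libraries held a smaller share of 26G reads and a larger share of 21U-like reads than both eri-6 wild-type libraries. The 26G class, primary siRNAs bound by the Argonautes ERGO-1 and ALG-3/4, made up 1.08% ± 0.108 of reads in eri-6 mutants (SD, n = 3) and 1.72% ± 0.401 in eri-6 wild type (SD, n = 2), with 1.21% in arl-8. Reads of 21 nt starting with T, the form of the germline piRNAs called 21U-RNAs, made up 8.99% ± 0.702 in eri-6 mutants (n = 3), 5.82% ± 0.524 in eri-6 wild type (n = 2) and 8.77% in arl-8. The 22G class, secondary siRNAs made by RNA-dependent RNA polymerases, overlapped between the groups, at 18.8% ± 1.98 (n = 3) and 20.5% ± 0.403 (n = 2). The panel of 70 miRNAs took 48.1% to 52.3% of reads in every library. The mgIs30 library stood apart from the other 5 in its make-up: miRNA reads with a changed first base came to 2.38% of panel reads there against 5.51% to 6.16% elsewhere, and reads of 28 nt to 1.38% against 0.253% to 0.345%.

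Loss of eri-6 function went with near-absence of a set of 26G siRNAs. Of the 263 26G sequences tested, 161 were lower in the 3 eri-6 mutants than in the 2 eri-6 wild-type libraries and 0 higher (edgeR quasi-likelihood test, adjusted p under the threshold; 180 had an unadjusted p under 0.05; DESeq2 was not run on this class). Together these 161 sequences made up 614 RPM in sur-5::gfp and 843 in mgIs30, against 23.3, 80.8 and 49.96 in eri-6; mgIs30, eri-6; sur-5::gfp and eri-6. The sequence GAGTAGATATCGTGTATGAGGTTTCA had the strongest fall, with 0 reads in all 3 mutants and a mean of 9.21 RPM in wild type, which made it at least 156-fold lower (floor of 3 counts over the 3 mutants; at least 98.2-fold without eri-6; sur-5::gfp and 97.03 without eri-6, where the floor covers fewer reads). The median log2 ratio of the 161 sequences was -4.82 from pooled reads, with sequences under 3 counts in the mutants at that floor.

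Levels in the arl-8 library, which was not part of the test, separated these 161 sequences. In 85 of them the arl-8 level was at least 50% of the wild-type mean, and this group held 23, 30 and 28 reads in all in the 3 eri-6 mutants against 7517 in sur-5::gfp, 5252 in mgIs30 and 9650 in arl-8. In 73 others the arl-8 level was under 25%, and their total in the 3 mutants stood at 6.03% to 22.3% of the wild-type mean, beside 8.78% in arl-8. That mean rested largely on mgIs30, at 532 RPM, with 180.1 in sur-5::gfp and 79.2 in eri-6; sur-5::gfp. In the same 4 libraries, the 3 mutants and arl-8, antisense MSP 26G reads were at 2.74 to 10.2 RPM, against 29.4 in sur-5::gfp and 54.4 in mgIs30, and the mir-35 family at 11.3% to 13.6% of miRNA reads, against 7.16% and 6.02%. The limits of 50% and 25% were set after the data had been seen. Without eri-6; mgIs30, without eri-6 or without mgIs30 the number of lower sequences was 99, 92 or 93, and with the transgene pairs as a block it was 0 on 4 libraries (86 at an unadjusted p under 0.05), where the adjusted p of the named sequence rose to 0.0577. Without sur-5::gfp or mgIs30, 6 or 4 sequences were higher, where the lone remaining wild-type library is assumed to vary like the mutants.

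**Figure D1:**
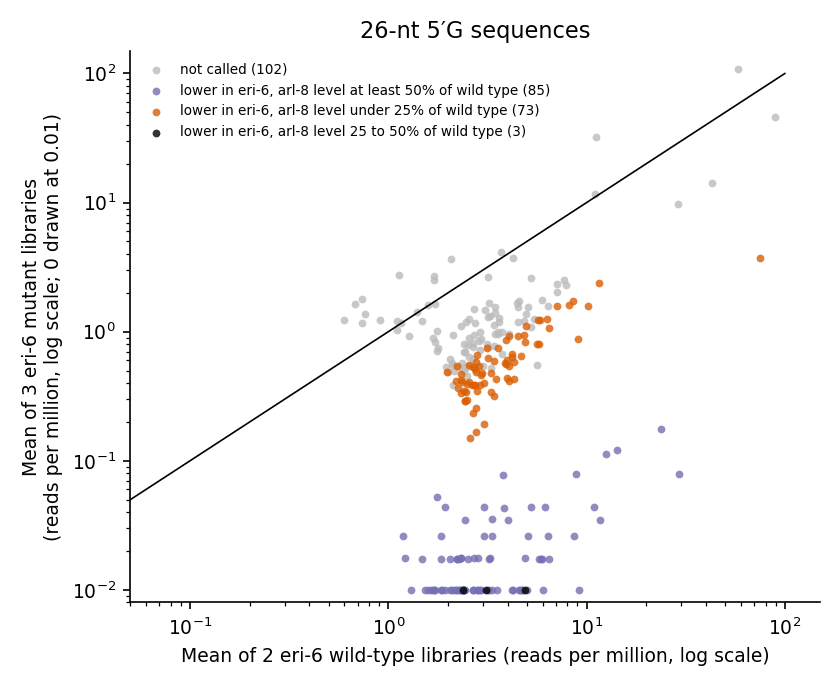
Levels of the 263 tested 26G sequences, as the mean of the 2 eri-6 wild-type libraries (x axis) against the mean of the 3 eri-6 mutant libraries (y axis), both in RPM on log scales, with 0 drawn at 0.01 and a line of equal levels. Colours divide the 161 lower sequences by their arl-8 level: the 85 kept at 50% or more lie near the bottom of the plot and the 73 under 25% lie closer to the line.

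Secondary 22G siRNAs were lost in eri-6 mutants from a limited set of sequences. Of 15382 22G sequences tested, 545 (3.54%) were lower and 0 higher (edgeR quasi-likelihood test, adjusted p; 1458 at an unadjusted p under 0.05; DESeq2 called 608 lower and 10 higher). All 545 were lower in both within-transgene pairs, whose libraries were also in the test, so this is no separate support. They summed to 4467 and 4884 RPM in sur-5::gfp and mgIs30, to 2820 in arl-8, and to 75.9, 83.3 and 69.9 in eri-6; mgIs30, eri-6; sur-5::gfp and eri-6. The strongest fall was that of GTTCTAAGTCCAATAGTAGAAT, with 0 reads in the mutants and a mean of 20.8 RPM in wild type (8.11 in sur-5::gfp and 33.6 in mgIs30), at least 353-fold lower (edgeR adjusted p = 0.0173). This bound became 137-fold without mgIs30, 569 without sur-5::gfp, 222 without eri-6; sur-5::gfp and 220 without eri-6. The adjusted p was 0.0624 without eri-6; mgIs30 and 0.0674 without eri-6. The median log2 change of the 545 was -6.94 as fitted and -5.82 from pooled reads, with sequences under 3 counts in the mutants at that floor. The arl-8 library held 61.1% of the wild-type level at the median sequence and under 25% at 17 of the 545. These sequences were chosen for their level in the same wild-type libraries, without arl-8. A lower level in arl-8 can come in part from that choice, so 61.1% does not measure a loss in arl-8. None of the 545 matched a transgene query.

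Among loci with enough reads of both classes, 22G and 26G siRNAs were lost largely together. When overlapping sequences were joined, 1592 loci could be tested for both. At 241 of them 26G reads were lower, and 187 of those 241 (77.6%) also had lower 22G reads, against 29.1 for independent lists. Among the 1351 loci whose 26G reads were not lower, 5 (0.370%) had lower 22G reads. Both classes were counted in the same libraries, so the lists are not independent. Within a locus 22G and 26G reads were joined by overlap, so shortened 26G reads could count as 22G reads. How far this raised the joint loss was not tested. By arl-8 level, split at limits set after the data had been seen and without a test of the difference, 164 of the 206 loci with 26G reads kept in arl-8 had lower 22G reads, with a median log2 change of -5.32, against 4 of the 15 loci with 26G reads low in arl-8, with a median of -1.76. Reads in arl-8 also counted toward the read limits of loci. In all, 632 of 21647 22G loci and 1181 of 4503 26G loci were lower, most of them not tested for the other class. Of the 1181, 723 were under 25% of the wild-type mean in arl-8, where MSP 26G reads were also low (3.05 RPM) and the mir-35 family high (12.2%), and 400 at 50% or more. The number of lower 26G loci became 287 without eri-6; mgIs30, 421 without eri-6; sur-5::gfp, 420 without eri-6, 1779 without sur-5::gfp, 369 without mgIs30 and 0 with the transgene pairs as a block.

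For 22G sequences, leaving out 1 library moved the number of lower calls to 356 (without eri-6; mgIs30), 341 (without eri-6) or 1199 (without sur-5::gfp), of which 355, 339 and 498 were among the 545. Higher calls numbered 909 without sur-5::gfp, 259 without mgIs30 and 1 without eri-6. The fit with the transgene pairs as a block called 377 lower, 370 of them among the 545.

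22G siRNAs of the Tc1 transposase, histones and actin remained above the level of their reversed proteins in the eri-6 mutants. Antisense 22G reads of the Tc1 transposase, an enzyme of a DNA transposon, stood at 503 ± 93.2 RPM in eri-6 mutants (n = 3), 503 ± 29.5 in eri-6 wild type (n = 2) and 513 in arl-8, with 2.41 and 3.00 for the reversed protein. Antisense 22G reads of histone H3 stood at 13.7 ± 1.17 in mutants and 21.7 ± 5.21 in wild type, and those of histone H4 at 27.8 ± 4.32 and 33.9 ± 7.23 RPM. The actin level in mutants, 8.46 ± 4.01, was 0.651 times the wild-type mean. The exact two-sided permutation p was 0.2 for histone H3, 0.4 for histone H4 and for actin, and 1 for Tc1, and 3 libraries against 2 cannot give a p below 0.2.

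Antisense siRNAs of MSP were lower in the 3 eri-6 mutants and in arl-8 than in both eri-6 wild-type libraries. Antisense 26G reads of MSP, the cytoskeletal protein of nematode sperm and a known ALG-3/4 target, stood at 29.4 RPM in sur-5::gfp and 54.4 in mgIs30, and at 2.74, 10.2 and 8.63 in eri-6; mgIs30, eri-6; sur-5::gfp and eri-6. The arl-8 library held 3.05 RPM (95% Poisson interval 2.24 to 4.07). The ratio of the eri-6 mutant mean to the wild-type mean was 0.172 for MSP 26G reads and 0.429 for MSP 22G reads, each with an exact two-sided permutation p of 0.2, the smallest this design can give (n = 3 and n = 2). Actin 26G reads, few in number, had a ratio of 0.1996 (1 to 5 reads per library in the mutants and arl-8, 18 in sur-5::gfp and 13 in mgIs30). Levels of the embryonic mir-35 family ran the other way, and because the libraries fell into separate groups on that axis, a relation between the measures cannot be tested.

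**Figure D2:**
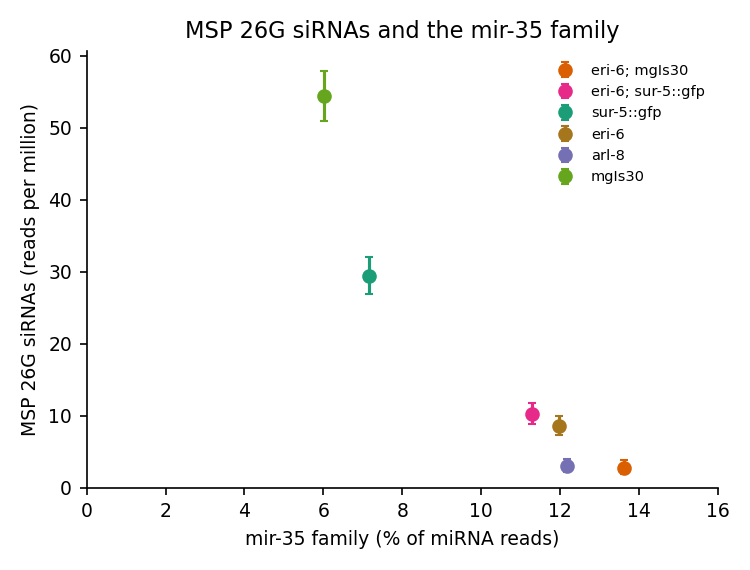
MSP antisense 26G RPM (y axis, bars are 95% Poisson intervals of counting error) against the share of the mir-35 family in miRNA reads (x axis, percent), 1 point per library. The sur-5::gfp and mgIs30 libraries lie at 7.16% and 6.02% on the x axis with 29.4 and 54.4 RPM, and the other 4 lie at 11.3% or more with at most 10.2 RPM.

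miRNAs, which do not depend on RNA-dependent RNA polymerases, served as a control class. The mir-35 family, expressed in embryos and in the germline of gravid adults, made up 12.3% ± 1.2 of miRNA reads in eri-6 mutants (SD, n = 3), 6.59% ± 0.810 in eri-6 wild type (n = 2) and 12.2% in arl-8. Its most abundant member, mir-39, had a log2 change of 1.12 ± 0.35 (approximate SE, edgeR adjusted p = 0.2535). None of its 8 members passed the test over all miRNAs, and 6 were higher when adjusted over the list alone, which became 0 with the transgene pairs as a block. The family's median log2 change was 1.13 (camera in limma, adjusted p = 4.08e-07 with the preset correlation; adjusted p = 0.0727 with an estimated correlation). The mir-51 family had a median log2 change of 0.22 (camera adjusted p = 0.431, and 0.634 with an estimated correlation), with 0 of 6 members higher over the list alone.

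No single miRNA of the 70 passed the edgeR test (11 had an unadjusted p under 0.05), while DESeq2 called 6 higher and 1 lower. Log2 changes of the most abundant members of the other families were -0.07 ± 0.25 for mir-58, 0.25 ± 0.36 for mir-55 of the mir-51 family, -0.69 ± 0.28 for mir-48 of the let-7 family and -0.66 ± 0.23 for lin-4 (approximate SE). The let-7 family, which times late larval development, made up 1.63% ± 0.221 of miRNA reads in mutants and 2.77% ± 1.18 in wild type, and the lin-4 family 1.68% ± 0.198 and 2.61% ± 0.799. Without sur-5::gfp, 21 miRNAs were higher and 18 lower, and without mgIs30 1 was higher. In the fit without sur-5::gfp the log2 changes of mir-39, mir-55, mir-48 and lin-4 were 1.67, 0.91, -1.05 and -0.91, all past the threshold. That of mir-55 was -0.18 without mgIs30, and that of mir-58 was 0.01 without eri-6 and 0.08 without mgIs30.

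The next comparison addressed siRNAs made against transgenes. Antisense reads of GFP were abundant in all 4 transgenic libraries and at the counting floor without a transgene: 302 RPM in sur-5::gfp, 248 in eri-6; sur-5::gfp, 161 in eri-6; mgIs30 and 28.6 in mgIs30, against 1 read each in eri-6 and arl-8. Reads of bla, the ampicillin resistance gene of cloning vectors, were found in the same 4 libraries, at 456, 162, 38.1 and 28.97 RPM in that order. Antisense lacZ reads occurred at 87.5 RPM in mgIs30 and 4.39 in eri-6; mgIs30, and at 0 or 1 read in each of the other 4. In the 4 carriers 67.9% to 73.9% of the antisense GFP reads were 22G. The one-sided exact permutation p of carriers against non-carriers was 0.0667 for GFP, bla, lacZ and the unc-54 3′ UTR, the smallest that these splits of 4 against 2 libraries allow (adjusted over 4 comparisons, 0.0667).

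**Figure D3:**
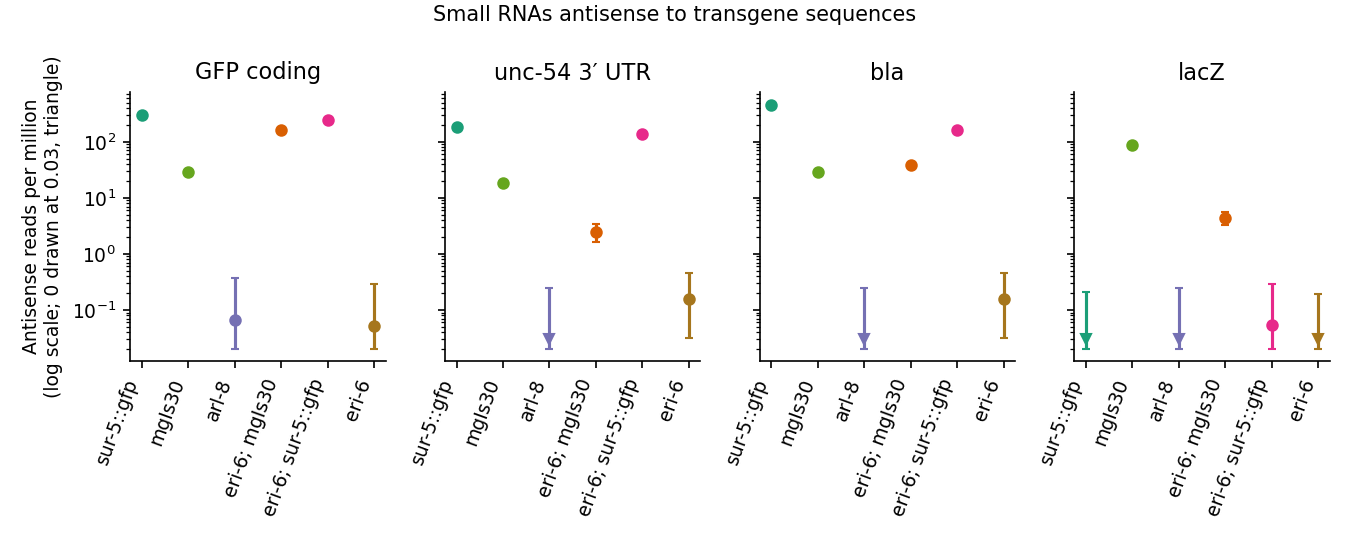
Antisense RPM (log scale) of the GFP coding sequence, the unc-54 3′ UTR, bla and lacZ in each of the 6 libraries, with 95% Poisson intervals of counting error; triangles at 0.03 mark 0 reads. GFP reads lie between 28.6 and 302 RPM in the 4 transgenic libraries, and lacZ reads fall from 87.5 in mgIs30 to 4.39 in eri-6; mgIs30.

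In sur-5::gfp, all 3 queries had fewer antisense reads in the eri-6 mutant, by different amounts. The ratio of eri-6 to wild type was 0.821 for GFP (95% interval 0.790 to 0.854), 0.733 for the unc-54 3′ UTR (0.696 to 0.772) and 0.355 for bla (0.340 to 0.370). Each ratio sets 1 library against 1 and has no replicate check, so it compares these libraries and not the genotypes.

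In mgIs30 the parts of the array went in opposite directions. Antisense lacZ reads were 19.9-fold lower in eri-6; mgIs30 than in mgIs30 (interval 15.3 to 26.5), and reads of the unc-54 3′ UTR 7.64-fold lower (5.28 to 11.4). Antisense GFP reads were instead 5.63-fold higher (5.102 to 6.21), and bla reads 1.31-fold higher (1.16 to 1.49). These ratios also rest on 1 library each, and the mgIs30 library is the one with the separate make-up described above.

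**Figure D4:**
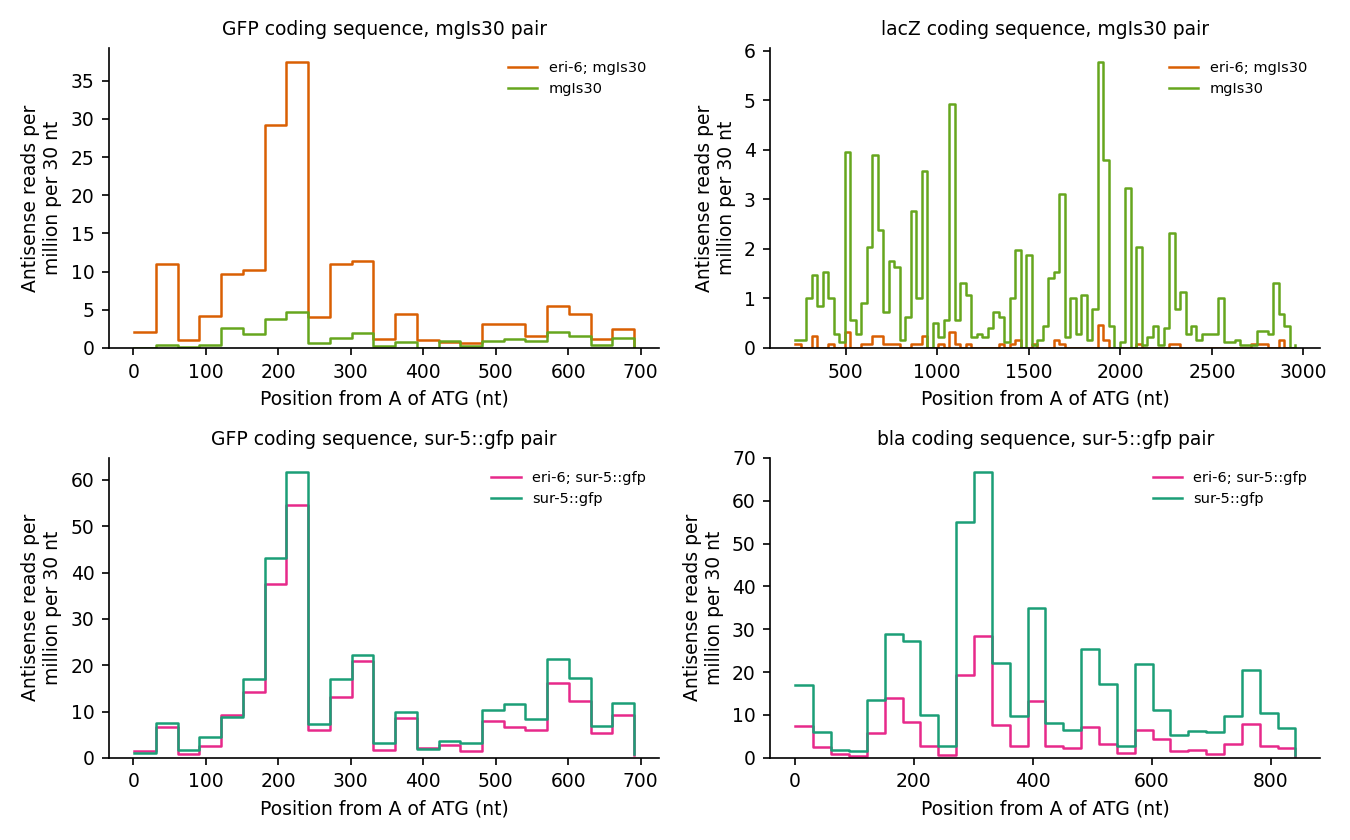
Antisense RPM in windows of 30 nt along the GFP, lacZ and bla coding sequences (x axis, position from 1 at the A of the ATG, in nt), with a line for each library of a pair; the panel for bla shows the sur-5::gfp pair. GFP reads of eri-6; mgIs30 lie above those of mgIs30 (161 against 28.6 RPM in all), and lacZ reads below (4.39 against 87.5).

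Among antisense GFP reads, more crossed exon junctions than boundaries of exon and intron. In sur-5::gfp, 415 antisense reads crossed an exon junction of the spliced GFP and 84 crossed a boundary between exon and intron. The counts were 380 and 79 in eri-6; sur-5::gfp, 156 and 31 in eri-6; mgIs30 and 48 and 12 in mgIs30. Antisense reads within the 3 introns numbered 49, 36, 15 and 7 in these 4 libraries, in the same order.

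The arl-8 comparison asked which 22G siRNAs depended on arl-8. The arl-8 library had few distinct changes against the 2 transgenic controls: 125 of 15392 22G sequences were at least 4-fold lower than in both controls and 4 were higher. The same count gave 369 lower and 267 higher for sur-5::gfp against arl-8 and mgIs30, and 523 and 79 for mgIs30 against arl-8 and sur-5::gfp. Without first-base variants the lower counts were 127 for arl-8, 369 for sur-5::gfp and 440 for mgIs30. Of the 125, 42 matched GFP, bla or the unc-54 3′ UTR, of which the arl-8 strain has only the UTR of its own unc-54 gene. Another 44 were under 25% of the controls also in the eri-6 library without a transgene. These 44 held 2552 reads in eri-6; sur-5::gfp and 155 in eri-6; mgIs30, against 69 in eri-6 and 92 in arl-8. As a set, their low level was thus not specific to the arl-8 mutation, which the eri-6 library lacks. Reads were many in eri-6; sur-5::gfp and few in eri-6, as a lack of transgene sequences would give. Some sequences went the other way. Among them were the 5 also lower in eri-6 mutants, with at most 12 reads each in eri-6; sur-5::gfp. Each level comes from 1 library, so an added effect of the arl-8 mutation stays open. A further 21 were low in arl-8 and in eri-6; mgIs30 but not in eri-6, with 1377 reads in eri-6, 54 in arl-8 and 57 in eri-6; mgIs30. The remaining 18 were a median of 5.02-fold lower.

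The largest rise in arl-8 was that of GAAAGCTGTGGAATGATTAGTC, with 65 reads in arl-8 against 4 in sur-5::gfp and 2 in mgIs30 (15.5-fold against the nearer control), followed by GTTCTGAGGGGGCTTTTACCAT, with 128 reads against 12 and 24 (5.68-fold). For 26G sequences with at least 20 reads and a mean of at least 1 RPM, limits set after the data had been seen, 119 of 470 were at least 4-fold lower in arl-8 than in both controls and 0 higher. The counts were 10 and 1 for sur-5::gfp and 19 and 32 for mgIs30. MSP 26G reads stood at 3.05 RPM in arl-8 against 29.4 and 54.4 in these controls, and the mir-35 family at 12.2% of miRNA reads against 7.16% and 6.02%. With 1 arl-8 library there was no test, and the number of lower 22G sequences became 556 at 2-fold, 57 at 8-fold and 1 of 2338 in CPM of miRNA reads, a scale on which the limit and the added count also weigh more. With miRNA reads as size factors and those unchanged it was 114.

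Few 22G sequences were at least 4-fold lower in arl-8 and also lower in eri-6 mutants. Sequences of a transgene can be low in arl-8 merely because that strain carries no transgene, while 2 of the 3 eri-6 mutants carry one. None of the 545 sequences lower in eri-6 mutants matched a transgene query. Sequences that match a query or were at least 4-fold higher in a transgenic eri-6 mutant than in eri-6 were therefore left out, a choice made after the data had been seen. Of the 15060 others in both comparisons, 55 were lower in arl-8 and 5 of these also in eri-6 mutants, against 1.99 for independent lists. At 2-fold for arl-8, 75 of 460 were lower in both, against 16.6 for independent lists. Both comparisons use the same 2 control libraries. In 20 simulations of unchanged libraries, lists as long as the real ones from the top of each ranking shared a mean of 7.7 sequences (2 to 15) at the length of the 4-fold list. At that of the 2-fold list they shared 54.9 (46 to 63), against the real 75. A mean of 0 simulated sequences passed the eri-6 test, so the simulated eri-6 lists hold noise only, unlike the real calls. These means are thus no baseline for the real overlaps, and whether either overlap exceeds the effect of shared controls cannot be told.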

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

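The tests on transgene siRNAs in this part were chosen after the ratios had been seen.

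The GFP ratios of eri-6 to wild-type libraries lay on opposite sides of 1 in the 2 transgenes: antisense GFP reads were 5.63 times the wild-type level in mgIs30 and 0.821 times in sur-5::gfp. The difference between the transgenes was not tested, since each ratio sets 1 library against 1. Reads from a sur-5::gfp library mixed into eri-6; mgIs30 would bring unc-54 3′ UTR reads along. The eri-6; mgIs30 library had 1.51 of these per 100 GFP reads, against 54.8 and 61.4 in the sur-5::gfp libraries. It differed from its own control as well: mgIs30 had 328 antisense UTR reads beside 505 of GFP, and eri-6; mgIs30 had 31 beside 2052. A lower depth or yield of 1 library would move GFP and lacZ together, but their log2 ratios differed by 6.81. The ratio of 0.821 (interval 0.790 to 0.854) has counting error only and no spread between libraries, so a like effect of eri-6 in both transgenes and differences between single libraries cannot be told apart; a change of the mgIs30 array during strain construction may also play a part and was not tested.

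Antisense bla reads also moved apart, at 1.31 times the wild-type level in mgIs30 and 0.355 times in sur-5::gfp; this difference was not tested either. Sense bla reads were lower in the eri-6 library of both pairs, at 0.232 times in mgIs30 (interval 0.152 to 0.343) and 0.284 times in sur-5::gfp (0.270 to 0.297).

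Sense reads of the transgenes lie outside the comparisons above and exceeded the libraries without a transgene or, for lacZ, without mgIs30. The exceptions were the unc-54 3′ UTR and the GFP introns in eri-6; mgIs30. That library had 0 sense reads of the UTR, against 1 each in eri-6 and arl-8, and 0 of the introns, as in eri-6 and arl-8. Sense bla reads reached 424 RPM in sur-5::gfp, against 0.208 and 0.266 in eri-6 and arl-8. Sense GFP reads reached 41.01 RPM in sur-5::gfp, against 0 in both libraries without a transgene. Sense reads of the unc-54 3′ UTR reached 21.7 RPM in sur-5::gfp, and sense lacZ reads 18.6 RPM in mgIs30.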

How the results depend on the processing

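Alternatives were fixed in advance except the loci, the length windows, the minimum of 20 reads, the removal of first-base variants, miRNA reads as size factors for arl-8, the overlap without transgene sequences, all reads as library size and every alternative on MSP or on shares of reads, which were chosen after seeing the data. Of 162 alternatives to 26 counts and values, 56 changed a call or moved by more than their spread or 1.5 times the main count; no alternative run did so for ratios of shares, MSP ratios and transgene ratios. The number of lower 22G sequences (545) became 50 with at least 10 RPM in 2 libraries and fewer sequences tested, 841 at 21 to 23 nt and 973 with a minimum of 20 reads, and ranged from 341 to 1199 when 1 library was left out. Higher 22G sequences (0) became 10 with DESeq2 and 5 with a minimum of 20 reads, and ranged from 0 to 909. Lower 26G sequences (161) became 499 with a minimum of 20 reads and 0 with the transgene pairs as replicate block, on fewer libraries, and ranged from 92 to 169; higher ones ranged from 0 to 6. Called miRNAs (0) became 1 lower and 6 higher with DESeq2, and ranged from 0 to 18 lower and 0 to 21 higher. Lower 22G loci (632) stayed within 1.5 times, from 473 to 824; higher ones (2) became 0 with the block and 50 with DESeq2, and ranged from 0 to 462. Lower 26G loci (1181) became 0 with the block and ranged from 287 to 1779; higher ones (6) became 0 with the block and 11 with miRNA reads as library size, and ranged from 0 to 77. The mir-35 family's adjusted p was 0.0727 with an estimated correlation and 0.316 with the block as well. The log2 change of mir-58 turned to 0.01 with the block or without eri-6 and to 0.08 without mgIs30, with a range of -0.18 to 0.08 when 1 library was left out. That of mir-55 turned to -0.18 without mgIs30, with a range of -0.18 to 0.91. Lower arl-8 sequences (125) became 556 at 2-fold, 57 at 8-fold, 1 in CPM of miRNA reads, with fewer sequences tested, 29 at a mean of at least 50 and 35 with a pseudocount of 5; higher ones (4) became 264, 1, 0, 1 and 2. With miRNA reads as size factors, and limit and pseudocount unchanged, they were 114 lower and 9 higher. The overlap (5) became 75 at 2-fold and stayed at 5 without transgene sequences. Except for fewer sequences or libraries tested, the cause was not tested. The replicate block was the transgene, shared by a mutant and a wild-type library in each pair, and left 377 lower 22G sequences. Reads with a single genomic match, antisense reads of any length per gene, reads outside structural RNA as library size and the block for the fixed lists of siRNA target genes were not run, for lack of a genome sequence here. A count of 0 leaves levels up to 0.235 RPM open.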

Other observations

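Except for the search for 1-mismatch forms, the tests and limits in this part were chosen after the result was seen.

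Sequences high in both sur-5::gfp libraries went beyond the queries. In both sur-5::gfp libraries 189 22G sequences were at least 4-fold above the other 4 libraries, of which 29 matched GFP, bla or the unc-54 3′ UTR and 160 did not. Whether these 160 come from the transgene was not tested. No 22G sequence with at least 100 reads met the same limit in both mgIs30 libraries. GFP sequences could hardly meet it, since antisense GFP stood at 302 and 248 RPM in the sur-5::gfp libraries against 28.6 in mgIs30. Antisense lacZ had only 56 reads in eri-6; mgIs30. The 0 thus does not show that mgIs30 lacks siRNAs of its own.

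The mir-35 family was high and MSP 26G siRNAs low in all 3 eri-6 mutants and in arl-8. Against the eri-6 mutation alone stands arl-8, at 3.05 RPM of MSP 26G reads (2.24 to 4.07), and against the separate make-up of the mgIs30 library stands sur-5::gfp, at 29.4 RPM (26.96 to 32.1) beside 10.2 in the highest of the other 4 libraries. Each is a single library with counting error only, so both explanations stay open. A difference in developmental stage could account for both measures, since sperm form before embryos; the late-rising let-7 family exceeded the highest of the other 4 libraries by only 0.113 percentage points in the lower of the 2 libraries, against a range of 0.434 among the 4, so stage and genotype cannot be told apart here. With 2 groups of points on the mir-35 axis, no correlation was computed.

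A set of 83 22G sequences from 60 loci was missing from the sur-5::gfp library alone, with 58 reads in all there; the limit was a level of at least 2 RPM in every other library and a 20-fold deficit. The same limit gave 70 sequences for mgIs30, 4 for eri-6, 1 for arl-8 and 0 for eri-6; sur-5::gfp. First-base variants were not removed here. Variants of panel miRNAs starting with G came to 0.147% of panel reads in mgIs30 against 1.54% to 1.73% elsewhere. Part of the 70 may be such variants, which was not tested. Against depth, the library with the fewest reads, eri-6; mgIs30, had 0 sequences missing from it alone. Against the transgene itself, 1 of 85 sequences (1.18%) lost from sur-5::gfp, chosen without regard to eri-6; sur-5::gfp, was under 25% there too; that library also carries the eri-6 mutation. Single-base strain variants are argued against by a share of 0% of the 83 with a 1-mismatch form private to this library. A deletion or a heritable loss of silencing at these loci remains a hypothesis, which these sequences without positions could not test.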
